A study of Mus musculus with 6 samples.

How the data were processed

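The deposited table holds raw counts of sequenced reads or fragments per gene symbol, 1 column for each of 6 libraries, with 52997 symbols, of which 13507 had 0 counts in all libraries. Per the labels' protocols, 1000 cells per library were sorted in duplicate passes into lysis buffer. Polyadenylated RNA was copied into cDNA from an oligo(dT) primer, amplified by a limited PCR, cut and tagged with a transposase and sequenced as paired reads of 25 bases on a NextSeq500. STAR 2.5.4 and featureCounts on mm10 are named in the submitters' processing notes. The annotation release, the strand setting, the treatment of reads with several alignments and the markers used for sorting are not given in the sources used here. The protocol describes no molecular identifiers, so PCR copies of 1 molecule can be counted more than once, and counting intervals and floors cover counting error only. Because strand use is not stated, reads of overlapping antisense genes cannot be told apart.

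Columns were assigned to tissue by their names. The lymph node columns match the sample titles. The muscle columns are numbered 2, 3 and 4, while the muscle titles are numbered differently, so these columns were used as 3 muscle replicates without a link to single samples. No column was left unmatched. Total counts ran from 415460 to 2397134 per library. Symbols were matched to GENCODE release M21 (GRCm38, the assembly also called mm10), where 49439 of 52997 symbols (93.3%) were found, and coordinates come from that annotation. As a measure of ambiguous reads, the percent of each gene's 25-base words that also occur in transcripts of other genes was computed, and genes above 50% were passed over when genes were named. Satellite-overlapping models (14) and ribosomal RNA-like models (4) were chosen by name for the shares given per library, after the counts were seen. Their overlap with repeats was not computed.

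Tests used edgeR 4.0.16 in R 4.3.3 on the counts as deposited: filterByExpr (10823 genes kept), TMM scaling, and the quasi-likelihood F test (glmQLFit and glmQLFTest) on tissue alone over all 6 libraries, two-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Log2 fold changes are muscle minus lymph node, their standard errors were taken as the size of the fold change divided by the square root of F, and CPM values are scaled by the TMM library size. At a handful of counts in a tissue such a standard error can fall below counting error and then understates the uncertainty. The common biological coefficient of variation was 0.265, and 0.151 without muscle library 4. Scaling left the median log2 fold change of all tested genes at 0.02. Where a tissue had 1 to 3 counts, a ratio with its exact 95% binomial counting interval is given, and against 0 counts a bound with a floor of 3 counts over the group.

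Before the data were examined, 47 gene lists were fixed from general knowledge, covering stromal biology, RNA quality and other cell types, together with the tests, the alternatives and the rule for named genes. The rule takes the 15 largest changes each way among called genes with at least 50 mean CPM in the higher tissue and no overlap between tissues. It adds up to 4 called members of each list by smallest p, and 15 genes given in advance whatever their result. Models without an official name and genes sharing reads with near-identical copies were passed over. It names 105 tested genes, of which 96 were called. Of these, 1 called gene is not reported here. Lists with at least 5 tested members (38) were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 38 lists. Alternatives used an estimated correlation or fry. Of the 12 lists called with the preset correlation, the immediate early and interferon-stimulated lists held with an estimated one.

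Alternatives to the main test were RLE, upper-quartile and total-count scaling, no filter, a stricter filter (10 CPM in at least 3 libraries), DESeq2 1.42.0, limma-voom, a test against a 2-fold change, summing a pair of muscle libraries, and leaving out each library. Further alternatives were added after the data were seen: leaving out repeat-derived models, limma-voom with library weights, a block by column number, and thinning each library to the total of muscle library 4. The procedure was tested on simulated data for this comparison, with 3 and 3 libraries drawn from the real means, dispersions and library sizes. Changes of 2-fold or 4-fold were planted in 200 genes of at least 20 mean CPM, and 10480 genes were tested. The complement list was also shifted by -1 on the log2 scale. No simulated library was made to stand apart as muscle library 4 does. edgeR recovered 88% of the 4-fold and 20% of the 2-fold changes with 3 false calls, DESeq2 94% and 41% with 15, and limma-voom 86% and 19% with 2.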

Results

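Messenger RNA was measured in mesenchymal stromal cells, the connective tissue cells that build matrix and support other cells, from 2 tissues of 8-week-old C57BL/6 mice under resting conditions. The cells came from hindlimb skeletal muscle or from lymph nodes pooled over inguinal, axillary, brachial and cervical sites. Each library was made from 1000 cells that had been sorted in duplicate passes. There were 3 libraries per tissue, described by the submitters as biological replicates. The titles of 2 muscle samples share a number, so whether the 3 muscle libraries come from separate animals is not known here. Below, n = 3 counts libraries. The muscle libraries are called 2, 3 and 4 and the lymph node libraries 1, 2 and 3, as the count table numbers them. Total gene counts were 1844874, 1256276 and 415460 in muscle libraries 2, 3 and 4. They were 1851940, 2397134 and 2300873 in lymph node libraries 1, 2 and 3.

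The first question was how alike the libraries were within and between tissues. Muscle libraries 2 and 3 resembled each other across genes (Pearson r = 0.952 of log2 CPM over the 10823 tested genes, which are not independent replicates). Lymph node pairs had r between 0.952 and 0.969. Muscle library 4 stood apart, with r = 0.705 and 0.702 to the other muscle libraries. Its r to the lymph node libraries was between 0.656 and 0.668, whereas muscle libraries 2 and 3 had r between 0.873 and 0.887 to the same libraries. The first principal component (67.8% of the variance) separated muscle library 4 from the other libraries, and the second (19.8%) separated the tissues among the remaining libraries. Gene models taken by name as satellite-overlapping, a set chosen after the counts were seen, held 16.5% of the counts of muscle library 4. They held 2.38% and 3.98% in muscle libraries 2 and 3, and between 0.186% and 0.272% in lymph node libraries. Muscle library 4 also held transcripts of blood cells: summed T cell markers reached 747 CPM there and between 13.7 and 29.2 CPM in the other 5 libraries. Summed B cell markers reached 3258 CPM against between 506 and 891 CPM, of which Ebf1, a gene that stromal cells also express, made up between 463 and 615 CPM in each library. Lymph node library 3 held 141 CPM of Ighm and 100.2 CPM of Igkc, where muscle library 4 held 639.8 and 661 CPM. The summed myeloid markers reached 895 CPM against between 48.5 and 73.9 CPM. No pair of libraries of 1 tissue agreed within sampling noise (chi-square per degree of freedom between 2.55 and 27.0).

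**Figure D1:**
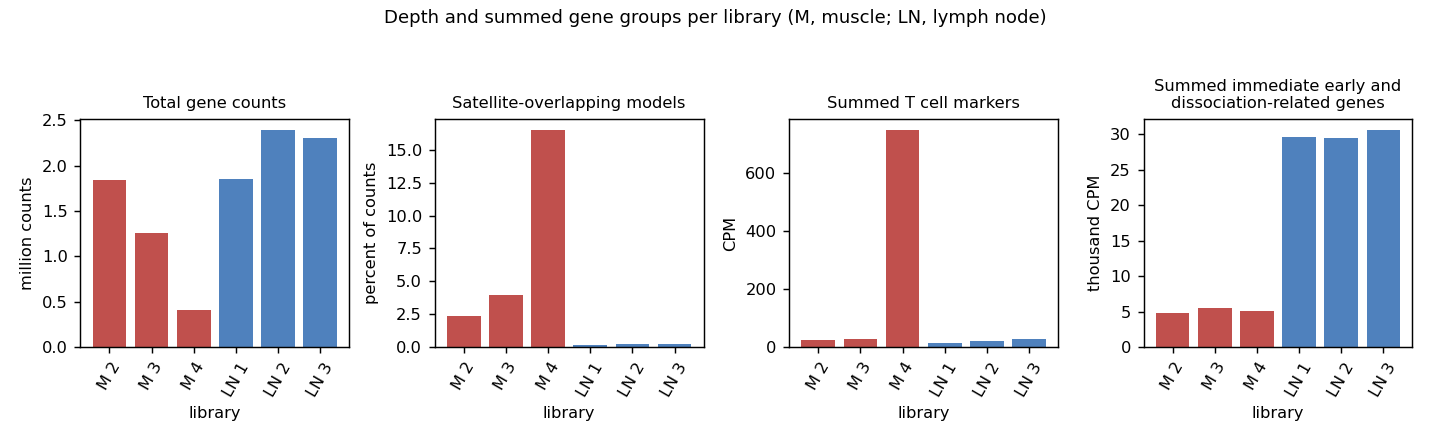
Bars give, for each of the 6 libraries (M, muscle in red; LN, lymph node in blue), the total gene counts, the percent of counts on satellite-overlapping gene models, the summed CPM of T cell markers and the summed CPM of immediate early and dissociation-related genes. Muscle library 4 has the lowest total, the highest satellite share (16.5%) and the highest T cell marker sum (747 CPM), and the lymph node libraries all exceed the muscle libraries in the immediate early sum.

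The main comparison asked which genes stromal cells of the 2 tissues express at different levels. Single genes higher in muscle cells include Comp, Thbs4, Cilp, Col8a1, Prg4 and Mfap4, which encode secreted proteins. Muscle cells were also higher in the retinoic acid-producing enzyme Aldh1a2, the thyroid hormone-activating enzyme Dio2 and the receptor Ret. Lymph node cells were higher in the B cell-attracting chemokine Cxcl13, the cytokine Il6, the chemokines Cxcl10 and Cxcl1, the matrix protease Mmp3, the lipid uptake receptor Cd36 and the immediate early genes Fos, Fosb and Atf3. Of 10823 genes tested, 468 (4.32%) differed at the 0.05 threshold, 158 of them higher and 310 lower in muscle (edgeR quasi-likelihood F test, two-sided, Benjamini-Hochberg adjusted). At least 2-fold changes made up 144 of the higher and 292 of the lower genes. Levels of the tissues did not overlap in 464 of the 468 genes, and in 2555 (23.6%) of all tested genes, where chance gives 10%. Muscle library 4 had a large effect on the count: without it 1391 genes were called, 539 higher and 852 lower, and all 468 genes kept their call and direction. Without muscle library 2 or 3 the count was 239 or 248, and without lymph node library 1, 2 or 3 it was 199, 142 or 160. With muscle libraries 2 and 3 summed into 1, 55 genes were higher and 167 lower. In that fit 23 of the named genes lost their call.

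Among the 15 genes with the largest increase in muscle, Comp, a cartilage matrix protein encoded on chromosome 8 at 70373558 to 70382066 (GRCm38), measured 99.1 ± 73.3 CPM in muscle and 2.61 ± 1.75 CPM in lymph node (SD, n = 3 each). Its log2 fold change, muscle minus lymph node, was 5.24 ± 0.65 (SE, edgeR adjusted p = 0.00222). Myoc, which encodes the secreted protein myocilin, measured 1899.9 ± 1147 CPM against 80.4 ± 50.2 CPM (4.56 ± 0.70, adjusted p = 0.00662). Hmcn2, which encodes the large extracellular protein hemicentin-2, was high and even in muscle at 2481 ± 114 CPM against 154 ± 76.1 CPM (4.01 ± 0.36, adjusted p = 5.23e-04). Aldh1a2 rose by 4.55 ± 0.71 (adjusted p = 0.00727) and Dio2 by 4.52 ± 0.40 (adjusted p = 4.68e-04). The hedgehog-binding protein Hhip rose by 4.34 ± 0.91 (adjusted p = 0.0284), with 358 CPM in muscle library 4 and 37.5 and 50.7 CPM in muscle libraries 2 and 3. The fold of the parathyroid hormone-like factor Pthlh was 15.3, that of the pyrophosphate-producing enzyme Enpp1 11.6, that of Ret, a receptor for glial cell line-derived factors, 8.14 and that of the proteoglycan Cspg4 8.03. All 15 were higher in all 3 muscle libraries than in any lymph node library, as the rule for naming them required. The adjusted p of Myoc, Thbs4, Prg4 and Mfap4 rose to 0.0579, 0.0579, 0.0649 and 0.0724 at most without lymph node library 2 or 3. That of Aldh1a2 rose to 0.0646 at most without lymph node library 1 or 3, and that of Hhip to 0.18 at most without any 1 lymph node library. Some folds moved by over 1.5 times when 1 library was left out. On the log2 scale Comp was 4.53 without muscle library 3 and 5.84 without lymph node library 3, Aldh1a2 3.96 without muscle library 2 and Hhip 2.74 without muscle library 4. Pthlh went from 3.94 to 4.63 and Col8a1 from 4.23 to 5.25 without lymph node library 2, and Mfap4 from 3.91 to 4.96 without lymph node library 1.

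Among the 15 genes with the largest decrease in muscle, Il6 (chromosome 5, 30013114 to 30019981, GRCm38) had 5 counts in all muscle libraries together and measured 154 ± 29.0 CPM in lymph node (log2 fold change -6.75 ± 0.53, adjusted p = 4.45e-04). Rgs16, a regulator of G protein signalling, had 2 muscle counts against 333 in lymph node, a ratio of 94.7 with a 95% counting interval from 26.0 to 785. Cxcl13 (chromosome 5, 95956951 to 95961068) measured 6.59 ± 7.09 CPM in muscle and 374 ± 34.7 CPM in lymph node (-5.49 ± 0.48, adjusted p = 4.68e-04). Cd36, with 8 muscle counts, measured 2.29 ± 0.65 CPM against 105 ± 11.8 CPM (-5.50 ± 0.32, adjusted p = 7.23e-05). At the few muscle counts of Il6 and Cd36 these standard errors understate counting error. Mmp3, also called stromelysin-1, measured 28.0 ± 12.6 CPM against 1201 ± 383 CPM (-5.29 ± 0.36, adjusted p = 2e-04). Fosb (-5.06 ± 0.26) and Atf3 (-5.01 ± 0.26) had the same adjusted p of 4.39e-05. The carbonic anhydrase Car3 was 34.0-fold lower, Cxcl10 33.7-fold, the oestrogen sulfotransferase Sult1e1 28.6-fold, the hyaluronan synthase Has1 24.2-fold and Cxcl1 23.2-fold. Car3, Cxcl10 and Sult1e1 had 7, 15 and 11 counts in all muscle libraries together, so the size of these folds is uncertain. The lipase inhibitor Angptl4 was 19.7-fold lower, the interleukin-1 decoy receptor Il1r2 19.4-fold and the cytochrome Cyp1b1 14.3-fold. All 15 kept their call without any 1 of the 6 libraries. The folds of Il6, Rgs16, Cxcl13 and Cxcl10 depend on muscle library 2 (2.64, 1.05, 14.8 and 7.38 CPM there and at most 0, 0, 2.69 and 0.77 CPM in the other muscle libraries). Without it the log2 fold changes of Cxcl13 and Cxcl10 were -7.25 and -7.67, and Il6 and Rgs16 had 0 muscle counts. Without muscle library 3 Il6 was -6.14. Angptl4 went from -4.30 to -5.03 without muscle library 2 and to -3.68 without muscle library 3. Without muscle library 3 Cyp1b1 went from -3.84 to -4.50 and Has1 from -4.60 to -5.34, and without lymph node library 2 Sult1e1 went from -4.84 to -4.11.

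**Figure D2:**
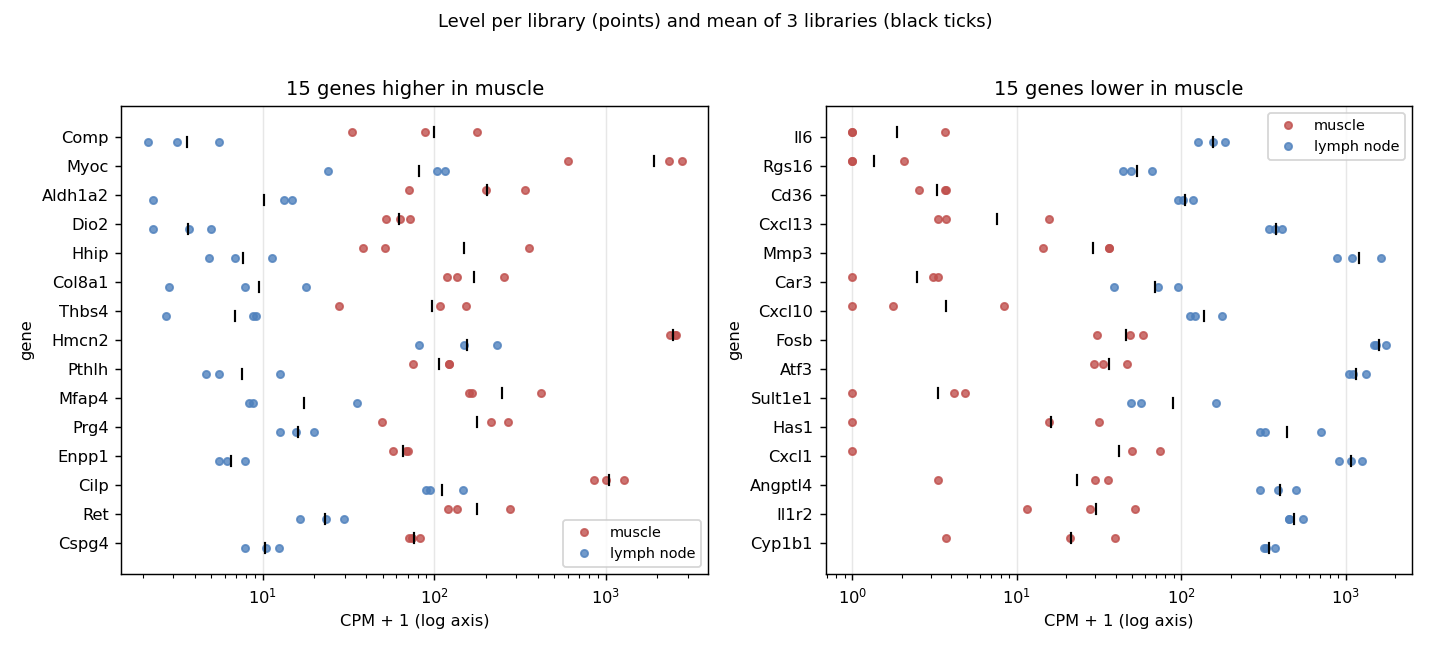
Points give CPM plus 1 on a log axis in each library (red, muscle; blue, lymph node) and black ticks the mean of 3 libraries, for the 15 genes with the largest increase (left) and decrease (right) in muscle among those at 50 CPM or more in the higher tissue. In each gene the 3 libraries of 1 tissue all lie above the 3 of the other, as the rule for naming required, and Hhip spreads from 37.5 to 358 CPM within muscle.

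Genes that respond within minutes to stress or tissue dissociation formed the group with the most calls. Of 38 tested immediate early and dissociation-related genes, 29 fell in muscle relative to lymph node, 0 rose and 9 were not called, and 30 fell adjusted over the list alone. The list's median log2 fold change was -2.19 (camera adjusted p = 5.53e-29, and adjusted p = 0.00665 with an estimated correlation). Together its genes made up 5199 ± 344 CPM in muscle and 29908 ± 621 CPM in lymph node (SD, n = 3 each). Fos measured 424 ± 81.2 CPM against 5409 ± 415 CPM (-3.67 ± 0.22, adjusted p = 7.23e-05), and Junb 303 ± 29.0 CPM against 2465 ± 79.1 CPM (-3.03 ± 0.18, adjusted p = 7.23e-05). When muscle library 4 was left out 32 members fell, and when lymph node library 2 or 3 was, 18 did. This sum moved with tissue in every library, so the inflammatory and signalling groups described next were measured in libraries that also differed in it.

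Of 25 tested genes of lymph node reticular cells, the fibroblasts that organise lymphoid tissue, 10 fell in muscle, 1 rose and 14 were not called (13 fell and 2 rose adjusted over the list alone, camera adjusted p = 9.61e-07, adjusted p = 0.181 with an estimated correlation). Those that fell include Il6, Cxcl13, the prostaglandin synthase Ptgs2 (-3.31 ± 0.24) and Cxcl10, and the member that rose was Prg4, a lubricating proteoglycan of joints that lost its call without lymph node library 2 or 3. The homeostatic chemokine Ccl19, below the filter for testing, had 0 counts in muscle and 17 in lymph node, which is at least 3.22-fold lower in muscle against a floor of 3 counts over the group. Ccl21a had 0 counts in all 6 libraries. The treatment of reads with several alignments is not given, so this 0 does not show that its transcript was absent. The stromal survival factor Il7 was low in both tissues (8.85 ± 5.66 CPM in muscle and 5.94 ± 1.60 CPM in lymph node, adjusted p = 0.596). Of 13 tested chemokines 6 fell and 0 rose (8 and 0 adjusted over the list alone, camera adjusted p = 3.25e-05, adjusted p = 0.324 with an estimated correlation). Cxcl12, which retains blood cell precursors and lymphocytes, fell from a high level, at 365 ± 35.7 CPM in muscle against 955 ± 27.4 CPM in lymph node (-1.39 ± 0.17, adjusted p = 0.00205). Of 24 tested cytokine and receptor genes acting on leukocytes 4 fell and 0 rose (5 and 0 adjusted over the list alone, camera adjusted p = 0.00132, adjusted p = 0.236 with an estimated correlation). They were Il6 and the receptor chains Il1r1 (-2.16 ± 0.31), Il1rap and Il17ra. Leaving out muscle library 4 gave 7 lower cytokine genes, and leaving out muscle library 3 or any 1 lymph node library gave 2. Il17ra lost its call without any 1 library other than muscle library 4 (adjusted p up to 0.129), and Il1rap without muscle library 3 or any 1 lymph node library (up to 0.104). Il33, an alarmin that acts on regulatory T cells in muscle, did not differ detectably, at 237 ± 43.9 CPM in muscle and 201 ± 48.5 CPM in lymph node (0.22 ± 0.23, adjusted p = 0.736).

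Of 45 tested interferon-stimulated genes, 16 fell in muscle and 0 rose (29 fell adjusted over the list alone, camera adjusted p = 3.29e-17, adjusted p = 0.0196 with an estimated correlation). The transcription factor Irf1 measured 78.5 ± 29.8 CPM in muscle and 590 ± 71.4 CPM in lymph node (-2.98 ± 0.27, adjusted p = 5.23e-04), and the GTPases Ifi47 (-3.44 ± 0.29) and Gbp2 (-1.83 ± 0.23) fell as well. With an estimated correlation and without muscle library 4 the list had an adjusted p of 0.125. The count was 34 without muscle library 4, 5 without muscle library 2, 7 without muscle library 3, and 5, 4 and 4 without lymph node library 1, 2 and 3. Of 22 tested genes of antigen presentation by MHC class I, 6 fell and 0 rose (14 fell adjusted over the list alone, camera adjusted p = 3.15e-09, adjusted p = 0.324 with an estimated correlation). B2m, the invariant light chain, measured 703 ± 149 CPM against 2016 ± 130 CPM (-1.53 ± 0.20, adjusted p = 0.00333). H2-D1 (-1.57 ± 0.17), H2-K1 (-1.87 ± 0.30) and H2-T23 (-1.18 ± 0.17) fell too, and are uncertain as single genes because 36.3%, 31.7% and 30.5% of their 25-base words occur in other genes. The class I count was 20 without muscle library 4, 4, 2 and 3 without lymph node library 1, 2 and 3, and H2-K1 and H2-T23 lost their call without lymph node library 2 or 3 (adjusted p up to 0.0594 and 0.0577). None of 5 tested MHC class II genes was called (4 rose adjusted over the list alone, camera adjusted p = 0.158, adjusted p = 0.755 with an estimated correlation), by edgeR, DESeq2 or limma-voom, and 4 had an edgeR unadjusted p under 0.05. Their median log2 fold change was 3.73 with all libraries and 0.20 without muscle library 4. Of 14 tested complement genes 6 fell and 0 rose (7 fell and 2 rose adjusted over the list alone, camera adjusted p = 0.00519, adjusted p = 0.444 with an estimated correlation). C3, the central complement protein, measured 1285 ± 741 CPM in muscle and 10486 ± 515 CPM in lymph node (-3.02 ± 0.46, adjusted p = 0.00611), C2 fell (-2.69 ± 0.27), with 45.9% of its words shared with other genes, and the inhibitor Serping1 fell (-0.92 ± 0.19), a call lost without any 1 library other than muscle library 4 (adjusted p up to 0.17). In the lymphotoxin and NF-kB pathway 3 of 27 tested genes fell and 1 rose (the same numbers adjusted over the list alone, camera adjusted p = 0.116, adjusted p = 0.755 with an estimated correlation). Nfkbia (-2.79 ± 0.30) and Nfkbiz (-3.61 ± 0.45), feedback regulators of NF-kB, fell, and the calls of Birc3 (-1.66) and Traf1 (3.38) were lost without any 1 library other than muscle library 4 (adjusted p up to 0.115 and 0.247). Without muscle library 4 Nfkbiz was -4.24 and Traf1 2.72, and without lymph node library 3 Traf1 was 4.11. The list was called lower without muscle library 4 (adjusted p = 0.00191, 6 genes lower), a call lost with an estimated correlation (adjusted p = 0.388). It was also called lower without lymph node library 2 (adjusted p = 0.0332, preset correlation).

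Matrix genes changed in both directions. Of 59 tested elastic fibre, proteoglycan and matricellular genes, 12 rose, 4 fell and 43 were not called (16 and 8 adjusted over the list alone, camera adjusted p = 0.182, adjusted p = 0.811 with an estimated correlation). Cilp, a matrix protein of cartilage, measured 1047 ± 213 CPM in muscle and 109 ± 31.8 CPM in lymph node (3.25 ± 0.27, adjusted p = 4.45e-04). Smoc2 measured 2318 ± 129 CPM against 566 ± 24.7 CPM (2.03 ± 0.17, adjusted p = 4.45e-04), and the TGF-beta-binding protein Ltbp4 1527 ± 383 CPM against 329 ± 81.6 CPM (2.22 ± 0.26, adjusted p = 0.00177). The matricellular gene Cyr61, also an immediate early gene, fell by 3.12 ± 0.25 (adjusted p = 4.45e-04). Leaving out muscle library 4 gave 21 higher and 11 lower genes and a list called with the preset (adjusted p = 0.036) but not an estimated correlation (adjusted p = 0.388). Without lymph node library 2 or 3 the higher genes numbered 5 or 6. Of 47 tested matrix remodelling enzymes and inhibitors 8 fell and 2 rose (14 and 3 adjusted over the list alone, camera adjusted p = 5.31e-04, adjusted p = 0.755 with an estimated correlation). The metalloproteases Mmp3, Adam12 (-3.06 ± 0.31) and Mmp27 (-2.45 ± 0.31) fell, and Adamtsl2, which binds microfibrils, rose by 2.73 ± 0.33 (adjusted p = 0.00194). Without muscle library 4, 7 rose and 16 fell. Without any 1 other library 1 rose. Of this list 7 fell without muscle library 2 or 3 and 3, 4 and 3 without lymph node library 1, 2 and 3. Of 25 tested collagens 1 rose (Col8a1, 4.23 ± 0.59, adjusted p = 0.00414, log2 fold change 5.25 without lymph node library 2) and 1 fell (Col6a5, -2.19 ± 0.45, adjusted p = 0.0253, lost without any 1 library other than muscle library 4, where 4 collagens rose and 2 fell). The collagen counts were the same adjusted over the list alone, the median was -0.13, the mean 0.04 and camera's direction lower (adjusted p = 0.725, adjusted p = 0.935 with an estimated correlation). Of 20 tested osteochondrogenic and tendon genes 4 rose and 3 fell (6 and 3 adjusted over the list alone, camera adjusted p = 0.934, adjusted p = 0.949 with an estimated correlation), with Comp and Thbs4 leading the increases and the immediate early factors Egr1 (-2.18 ± 0.24) and Egr2 (-3.59 ± 0.38, -4.42 without muscle library 2) the decreases. Comp was 4.53 without muscle library 3 and 5.84 without lymph node library 3. The number that rose was 7 without muscle library 4 and 2 and 1 without lymph node library 2 and 3.

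Of 23 tested adipogenic genes, 8 fell in muscle, 2 rose and 13 were not called (11 and 4 adjusted over the list alone, camera adjusted p = 0.00151, adjusted p = 0.181 with an estimated correlation). Besides Cd36, lipoprotein lipase Lpl measured 514 ± 126 CPM in muscle and 2039 ± 151 CPM in lymph node (-1.98 ± 0.22, adjusted p = 0.00136). The lipid droplet protein Plin4 measured 2.45 ± 0.77 CPM against 30.9 ± 0.77 CPM (-3.72 ± 0.42, adjusted p = 0.00143), and the fatty acid carrier Fabp4 2.66 ± 2.37 CPM against 28.2 ± 3.93 CPM (-3.94 ± 0.53, adjusted p = 0.00359). Plin4 had 8 muscle counts and Fabp4 6, so their standard errors understate counting error. Bmp4 rose by 1.82 ± 0.30 (adjusted p = 0.00856, up to 0.0842 without muscle library 3 or lymph node library 1 or 3), and without any 1 library other than muscle library 4 at most 1 adipogenic gene rose. Of 22 tested adventitial and perivascular fibroblast genes 3 fell and 0 rose (4 and 3 adjusted over the list alone, camera adjusted p = 0.0163, adjusted p = 0.811 with an estimated correlation). They were Has1, the adhesion protein Opcml (-1.91 ± 0.24) and Smpd3 (-1.52 ± 0.26, adjusted p up to 0.0808 without muscle library 3 or lymph node library 2 or 3). The list was not called without muscle library 4 (adjusted p = 0.228), where 5 members fell and 3 rose.

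Shared stromal identity genes were called about as rarely, with all libraries, as tested genes at large (4.32%). Of 28 tested pan-mesenchymal genes 1 rose, the tetraspanin Cd9 (1.94 ± 0.21, adjusted p = 0.00116), and 27 were not called (1 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.295, adjusted p = 0.811 with an estimated correlation). Pdgfra measured 1058 ± 360 CPM in muscle and 1408 ± 79.0 CPM in lymph node (-0.41 ± 0.26, adjusted p = 0.536), and Pdgfrb 278 ± 78.1 CPM against 278 ± 47.8 CPM (0.02 ± 0.24, adjusted p = 0.989). Cd34 (-0.07 ± 0.23, adjusted p = 0.941), Pdpn (-0.04 ± 0.22, adjusted p = 0.961) and Ly6a (-0.59 ± 0.26, adjusted p = 0.32, 37.4% of words shared) were not called either. In the fit without muscle library 4, 3 of 29 pan-mesenchymal genes rose and 5 fell. That is a larger share than the 1391 of 11246 genes called in that fit. With all libraries, the fry test for change in either direction gave the list an adjusted p of 0.00283.

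Genes of nerve communication, chosen because the study concerns nerve and stromal cell crosstalk in muscle, had calls on some members and in both directions. The fry test for change in either direction gave an adjusted p of 0.00711 for the neurotrophic list. It gave 0.0494 for the axon guidance list and 0.218 for the neuropeptide receptor list. Of 13 tested neuropeptide and neurotransmitter receptors 1 rose and 2 fell (4 and 4 adjusted over the list alone, camera adjusted p = 0.934, adjusted p = 0.949 with an estimated correlation). Ramp1, a subunit of the receptor for calcitonin gene-related peptide, measured 91.8, 79.9 and 18.8 CPM in muscle libraries 2, 3 and 4 and between 13.1 and 18.9 CPM in lymph node (2.05 ± 0.44, adjusted p = 0.0302). Its partner Calcrl measured 221, 194 and 26.9 CPM in the same muscle libraries and between 98.8 and 124 CPM in lymph node (0.50 ± 0.50, adjusted p = 0.731). Without muscle library 4 Calcrl was called higher in muscle (0.91, adjusted p = 8.09e-04) and Ramp1 had an adjusted p of 2.96e-06, whereas without any 1 of the other 5 libraries Ramp1 was not called (adjusted p up to 0.209). The receptor Adcyap1r1 (-1.23 ± 0.27) and the GABA receptor subunit Gabra3 (-2.01 ± 0.37) fell, calls lost without any 1 library other than muscle library 4 (adjusted p up to 0.181 and 0.0842). Of 14 tested neurotrophic factors and receptors 1 rose (Ret, 177 ± 86.7 CPM in muscle and 22.1 ± 6.54 CPM in lymph node, 3.03 ± 0.38, adjusted p = 0.00237) and 1 fell (Ntrk2, the receptor for brain-derived neurotrophic factor, -1.29 ± 0.17, adjusted p = 0.00346). That list had 2 and 1 calls adjusted over the list alone, a median of -0.40, a mean of 0.12 and a camera direction of lower (adjusted p = 0.633, adjusted p = 0.837 with an estimated correlation). The nerve growth factor receptor Ngfr, below the filter, had 5 counts in muscle and 18 in lymph node, of which 15 were in lymph node library 1. Of 42 tested axon guidance and neural adhesion genes 2 rose and 5 fell (6 and 6 adjusted over the list alone, camera adjusted p = 0.712, adjusted p = 0.811 with an estimated correlation). Robo1, a receptor for Slit proteins, rose by 2.14 ± 0.28 (adjusted p = 0.00272) and Epha3 fell by 2.36 ± 0.27 (adjusted p = 0.0014). Rgma rose (1.86 ± 0.31) and Slit3 fell (287 ± 79.9 CPM against 582 ± 40.6 CPM) with all libraries, with adjusted p up to 0.105 and 0.198 when any 1 of lymph node libraries 1 to 3 or muscle library 2 was left out, and Slit3 also without muscle library 3. Leaving out muscle library 4 gave 5 neuropeptide receptors higher and 4 lower, and 10 axon guidance genes higher and 9 lower, whereas without any 1 other library 1 axon guidance gene fell.

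Patterning genes tied to body position differed in part. Of 24 tested limb and mesoderm transcription factors 2 rose and 2 fell (3 and 4 adjusted over the list alone, camera adjusted p = 0.462, adjusted p = 0.755 with an estimated correlation). Meox1 measured 86.3 ± 11.4 CPM in muscle and 11.6 ± 6.50 CPM in lymph node (2.90 ± 0.36, adjusted p = 0.00235). Tbx4, a hindlimb identity factor, had 43 counts in muscle and 3 in lymph node, a ratio of 25.2 with a 95% counting interval from 8.07 to 127 (adjusted p = 0.0133, up to 0.11 without any 1 lymph node library). Its log2 fold change of 4.76 was 4.17 without muscle library 4 and 5.51 without lymph node library 2. Shox2 (-1.45 ± 0.26) and Gata6 (-2.59 ± 0.56) fell, calls lost without any 1 library other than muscle library 4 (adjusted p up to 0.111 and 0.19). Of 4 tested HOX cluster genes, of which 2 were posterior, 1 rose in each list, Hoxa10 (26.9 ± 13.1 CPM in muscle and 4.74 ± 2.13 CPM in lymph node, 2.56 ± 0.49, adjusted p = 0.0185, up to 0.129 without any 1 library other than muscle library 4). Adjusted over the list alone, 1 rose and 1 fell among the 4 and 1 rose among the 2, and both lists were too small for a set test. In the fit without muscle library 4, 6 patterning factors rose and 8 fell.

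Signalling lists had calls on some members. The fry test for change in either direction gave the FGF, PDGF, VEGF and HGF list an adjusted p of 1.01e-04. It gave the other lists of this paragraph between 0.0883 and 0.218. Of 28 tested FGF, PDGF, VEGF and HGF genes 5 rose and 3 fell (5 and 6 adjusted over the list alone, camera adjusted p = 0.648, adjusted p = 0.811 with an estimated correlation). Fgf10 fell by 3.56 ± 0.40 (adjusted p = 0.00131) and Pdgfrl rose by 2.45 ± 0.41 (adjusted p = 0.00942, up to 0.085 without lymph node library 2 or 3). In BMP and TGF-beta signalling 3 of 38 rose and 3 fell (4 and 4 adjusted over the list alone, camera adjusted p = 0.477, adjusted p = 0.853 with an estimated correlation). They include Inhba (2.78 ± 0.49, adjusted p up to 0.113 without any 1 library other than muscle library 4) and Id3 (-1.51 ± 0.22, up to 0.0577 without lymph node library 2). In WNT signalling 2 of 29 fell and 1 rose (3 and 1 adjusted over the list alone, camera adjusted p = 0.116, adjusted p = 0.811 with an estimated correlation). The WNT list was called lower without muscle library 3 (adjusted p = 0.0464, preset correlation). The WNT enhancer Rspo3 fell by 2.83 ± 0.33 (adjusted p = 0.00151). Its relative Rspo1 had 2 muscle counts against 63, a ratio of 17.9 with a 95% counting interval from 4.76 to 151 and 0 muscle counts without muscle library 2. Sfrp4 rose by 1.15 ± 0.27 (adjusted p = 0.0498). The Rspo1 and Sfrp4 calls were lost without any 1 library other than muscle library 4 (adjusted p up to 0.182 and 0.275). Of 11 tested hedgehog genes 1 rose, Hhip (3 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.377, adjusted p = 0.811 with an estimated correlation). Of 18 retinoid genes 1 rose, Aldh1a2, and 1 fell, Rarres2 (-1.29 ± 0.28, adjusted p up to 0.198 without any 1 library other than muscle library 4, 31.2% of words shared). The retinoid list had 1 and 3 calls adjusted over the list alone (camera adjusted p = 0.0956, adjusted p = 0.444 with an estimated correlation). Of 15 insulin-like growth factor genes 1 fell, Igfbp3 (-1.62 ± 0.33, adjusted p = 0.0252, up to 0.143 without muscle library 2 or any 1 lymph node library). That list had 1 higher and 3 lower calls adjusted over the list alone (camera adjusted p = 0.48, adjusted p = 0.811 with an estimated correlation). Without muscle library 4 the numbers that rose and fell were 6 and 8 for FGF, PDGF, VEGF and HGF genes, 5 and 8 for BMP and TGF-beta, 3 and 5 for WNT, 3 and 1 for hedgehog, 1 and 4 for retinoid and 2 and 3 for insulin-like growth factor genes. Without any 1 other library at most 2 genes of the FGF group and at most 1 of the BMP group rose.

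No gene was called by edgeR, with all libraries or adjusted over the list alone, among 10 Notch genes, 12 contractile genes, 22 cell cycle genes, 63 cytosolic ribosomal proteins, 48 nuclear genes of oxidative phosphorylation, 21 cholesterol synthesis genes and 8 mitochondrially encoded genes. The mitochondrially encoded list was higher in muscle by camera (median 0.37, adjusted p = 0.0236, adjusted p = 0.811 with an estimated correlation), and was not called without muscle library 4 (adjusted p = 0.298) or lymph node library 2 or 3 (adjusted p = 0.0884 and 0.085). The other camera adjusted p-values were 0.699 for Notch, 0.712 for contractile, 0.653 for cell cycle, 0.404 for ribosomal, 0.697 for oxidative phosphorylation and 0.0539 for cholesterol synthesis genes. Of these 184 genes 15 had an edgeR unadjusted p under 0.05, and DESeq2 and limma-voom called 1 each. Without muscle library 4 edgeR called 9 cholesterol synthesis genes higher, 5 cell cycle genes higher and 1 lower, 6 ribosomal genes lower and 1 contractile gene higher and 2 lower. In that fit camera called the cholesterol synthesis list higher (adjusted p = 4.79e-07) and the ribosomal list lower (adjusted p = 1.17e-05), calls lost with an estimated correlation (adjusted p = 0.467 and 0.279). With the preset correlation the cell cycle list was called higher without muscle library 3 (adjusted p = 0.0425) or lymph node library 1, 2 or 3 (adjusted p = 0.028, 0.0218 and 0.00878), and the cholesterol synthesis list without lymph node library 2 or 3 (adjusted p = 0.0315 and 0.0159).

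**Figure D3:**
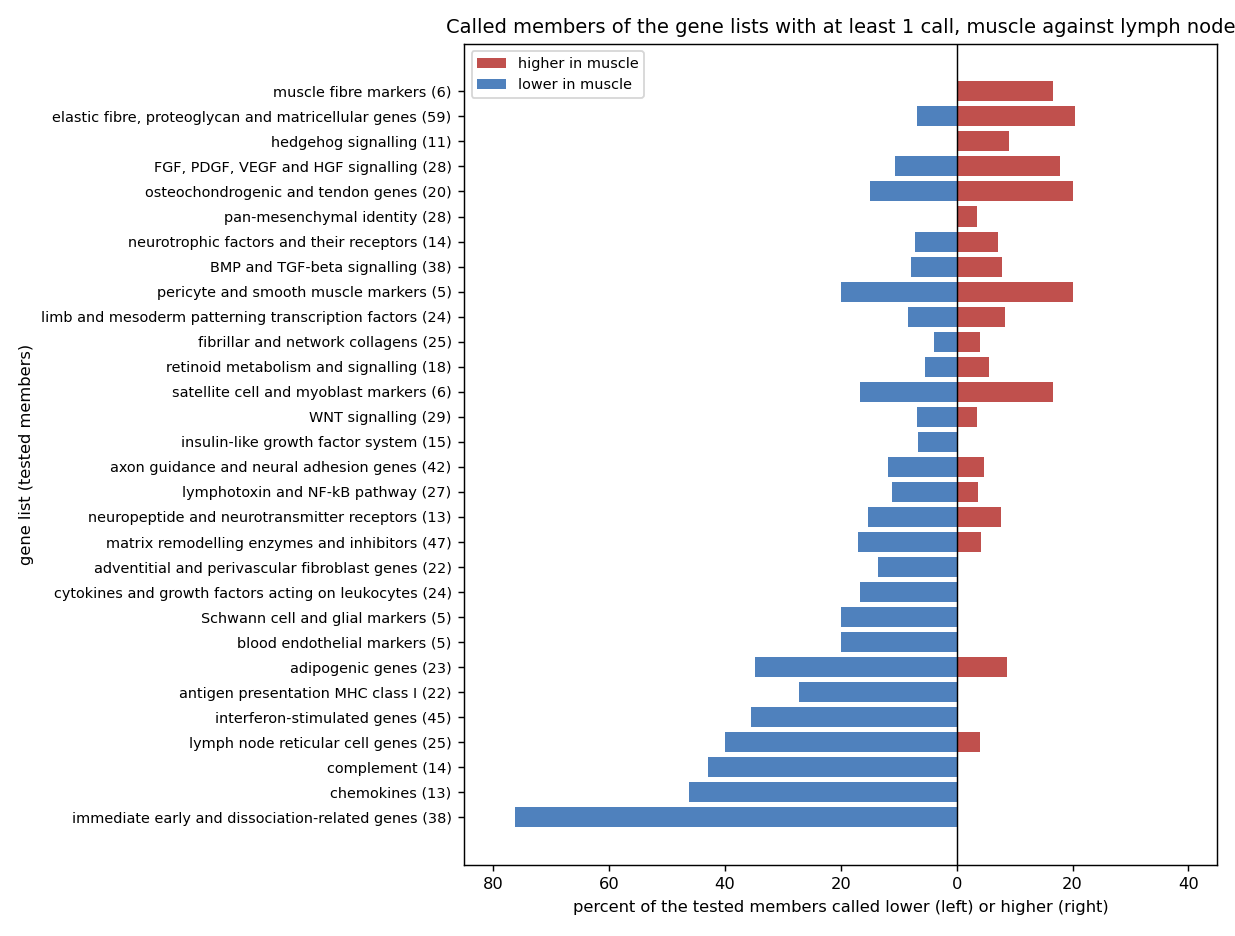
Bars give, for each list with a set test and at least 1 called member, the percent of tested members called lower (blue, to the left) or higher (red, to the right) in muscle, with the number of tested members in parentheses after the name. Immediate early and dissociation-related genes reach furthest to the left, with 29 of 38 members lower, and 12 of 59 elastic fibre, proteoglycan and matricellular genes lie to the right.

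Of 40 tested markers of other cell types 8 were called, 20 without muscle library 4, 5 without muscle library 2 and 4, 4 and 5 without lymph node library 1, 2 and 3. The leukocyte gene Ptprc measured 7.38, 9.22 and 589 CPM in muscle libraries 2, 3 and 4 and between 4.57 and 9.02 CPM in lymph node (4.60 ± 1.53, adjusted p = 0.165). No T cell gene, 3 B cell and 3 myeloid genes and 2 erythroid, platelet or mast cell genes were tested, with 0 calls (adjusted over the list alone, 1 myeloid and 1 erythroid gene rose). Over these and the lymphatic and neuronal lists, 3 of 14 tested genes had an edgeR unadjusted p under 0.05, DESeq2 called 1 and limma-voom 0. The endothelial gene Pecam1, below the filter, had 31 counts in muscle, of which 22 were in library 4, and 13 in lymph node. Of 5 blood endothelial genes 1 fell, Fabp4 (1 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.633, adjusted p = 0.811 with an estimated correlation), and of 3 lymphatic endothelial genes 0 were called in either way. Of 5 pericyte and smooth muscle genes Cspg4 rose and the channel subunit Abcc9 fell (-2.59 ± 0.30, adjusted p = 0.00143). Adjusted over the list alone, 2 rose and 1 fell, with a median of -0.41, a mean of 0.08 and a camera direction of higher (adjusted p = 0.938, adjusted p = 0.949 with an estimated correlation). Of 6 muscle fibre genes 1 rose, the calcium pump Atp2a1 (19.3 ± 13.6 CPM in muscle and 0.83 ± 0.36 CPM in lymph node, 4.27 ± 0.73, adjusted p = 0.0104, up to 0.0957 without any 1 lymph node library, 21.3% of words shared). Below the filter, Acta1 had 67, 42 and 0 counts in muscle libraries 2, 3 and 4 and 1 in lymph node. Its ratio was 192 with a 95% counting interval from 33.7 to 7638. Ckm had 20 muscle counts against 5, and Myh4 7 against 17. The muscle fibre list was higher in muscle (3 rose adjusted over the list alone, camera adjusted p = 0.00226, adjusted p = 0.181 with an estimated correlation). Summed levels were 251 ± 29.7 CPM against 99.9 ± 7.04 CPM, and 5 members rose without muscle library 4. Of 6 satellite cell genes Spry1 rose (1.31 ± 0.25) and Vcam1 fell (-1.68 ± 0.28), with adjusted p up to 0.151 without muscle library 2 or any 1 lymph node library and up to 0.0807 without muscle library 2 or 3 or lymph node library 1 or 2. That list had 2 higher and 1 lower calls adjusted over the list alone (camera adjusted p = 0.712, adjusted p = 0.837 with an estimated correlation). Of 5 Schwann cell and glial genes 1 fell, Egr2 (1 rose and 2 fell adjusted over the list alone, camera adjusted p = 0.116, adjusted p = 0.444 with an estimated correlation). Without muscle library 4 the list was called lower with the preset (adjusted p = 0.0144) but not an estimated correlation (adjusted p = 0.279). Of 3 neuronal genes 0 were called (1 rose adjusted over the list alone), and 2 rose without muscle library 4. The neuronal list, too small for a set test with all libraries, was called higher with the preset correlation without muscle library 3 (adjusted p = 0.0105) and without lymph node library 1, 2 and 3 (adjusted p = 0.0116, 0.00416 and 0.016). The 1 tested epithelial gene, Cldn3, had 2 muscle counts against 45, a ratio of 12.8 with a 95% counting interval from 3.34 to 109, a call lost without any 1 library other than muscle library 4 (adjusted p up to 0.159).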

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

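The added alternatives, chosen after the data were seen, are the library weights, the column-number block, the removal of repeat-derived models, the thinning and the estimated-correlation list tests without muscle library 4; the others were planned. No named gene or list changed direction past its threshold under any alternative run. RLE, upper-quartile and total-count scaling, the stricter filter, limma-voom, the removal of repeat-derived models and thinning left both counts of genes within 1.5 times 158 higher and 310 lower. The counts were 419 and 526 with no filter, 260 and 426 with DESeq2 (13 genes without an adjusted p), 39 and 102 against a 2-fold change and 552 and 814 with library weights (0.27 for muscle library 4). Which muscle columns share a title number cannot be told, so each pair was summed in turn: 55 and 167 with 2 and 3 summed, 563 and 872 with 2 and 4, and 494 and 772 with 3 and 4. Leaving out 1 library gave between 28 and 539 higher and between 114 and 852 lower genes, the lowest without lymph node library 2 and the highest without muscle library 4. The block by title number was not run, for the same reason. A replicate block by the table's column numbers, in which only numbers 2 and 3 occur in both tissues, gave 627 higher and 903 lower. Deviations from the group means correlated at -0.03 for number 2 and 0.02 for number 3. The muscle mean includes library 4, which stood apart and weighs on these deviations, so they cannot tell whether samples were paired. Lists called higher (2 with the preset correlation) numbered 0 with an estimated correlation, 1 with fry and 4 with muscle libraries 2 and 3 or 3 and 4 summed, and between 2 and 4 without 1 library. Lists called lower (10) numbered 2 with an estimated correlation and 10 with fry, though not the same 10. Fry did not call the adventitial, chemokine and matrix remodelling lists (adjusted p = 0.551, 0.0511 and 0.235). It called the blood endothelial, FGF group and Schwann cell lists lower (adjusted p = 0.0064, 0.0429 and 0.0429). The mitochondrially encoded list was not called higher by fry (adjusted p = 0.414). Called markers of other cell types (8) numbered 5 when restricted to markers at most at 10 CPM in the lower tissue, and between 4 and 20 without 1 library. Over the 500 most variable genes, median correlations were 0.287 within muscle, 0.352 between tissues and 0.93 within lymph node. Over the tested genes thinning took the median within lymph node from 0.956 to 0.921. Of the 96 called named genes, 59 kept their call without any 1 library and 37 lost it without at least 1; 19 of the 96 had a fold that moved by over 1.5 times without 1 library; 35 of the 96 lost their call in the test against a 2-fold change. Without repeat-derived models muscle library 4 still had at most r = 0.703 with muscle libraries 2 and 3, which had r = 0.951 with each other, a check also chosen after the data were seen. For the other differences the cause was not tested. Small changes were often missed in simulated data: the procedure recovered 20% of 2-fold and 88% of 4-fold changes. These were planted in genes of at least 20 mean CPM, in libraries of which none stood apart, so recovery may differ in the real data.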

Other observations

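The tests except the comparison of genes lower in library 4 and the splits of the libraries were chosen after the results were seen. The fit without muscle library 4 was planned, and its values were picked for this part after they were seen. In the fit without muscle library 4, the 9 of 21 cholesterol synthesis genes called higher in muscle had no called member in the other direction, and the list a median log2 fold change of 0.82 (camera adjusted p = 4.79e-07, adjusted p = 0.467 with an estimated correlation). Hmgcs1, which catalyses an early step, rose by 1.32 (adjusted p = 8.88e-05), and Fdft1, which forms squalene, by 1.43 (adjusted p = 0.00234). With all 6 libraries edgeR called 0 of the 21, with 5 at an unadjusted p under 0.05, DESeq2 called 0 and limma-voom 1. Antigen presentation by MHC class I had 20 of 22 members lower in the same fit and interferon-stimulated genes 34 of 45. These genes were named after their values were seen.

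Muscle library 4 stood apart from muscle libraries 2 and 3, and lower depth alone is argued against, because libraries 2 and 3 thinned to its total still had r = 0.927 with each other and at most 0.7295 with it. Of 54 T cell, B cell and myeloid markers with at least 5 counts, 46 were highest in that library, led by Igkc (661 CPM), Ighm (639.8 CPM) and Ptprc (589 CPM), after a sort for stromal cells whose markers are not given in the sources used here. At equal depth 98 genes were at least 4-fold lower in library 4 than in the mean of 2 and 3, and 64 were at least 4-fold higher. Between 2 and 3 the larger number in 1 direction was 0. RNA of leukocytes is argued against as the whole cause by the lower genes, because pan-mesenchymal genes had a median difference of only -0.57 on the log2 scale. A comparator of 0 is easily exceeded, so muscle libraries 2 and 3 were each diluted by that median, after the results were seen. This gave 4 and 3 genes at least 4-fold lower than in the other library. Loss of genes through fewer molecules cannot be told apart by this count. RNA of leukocytes as a part and fewer starting molecules stay open: the SD over 26 pan-mesenchymal genes was 1.98 times that between libraries 2 and 3, just short of the bound of 2 set for that explanation.

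Immediate early and stress genes were higher in all lymph node libraries. RNA of leukocytes from the node is argued against, because the summed T cell, B cell and myeloid markers without Ebf1 had a median in lymph node libraries 1.06 times the mean of muscle libraries 2 and 3 (95.9, 142 and 372 CPM against 117 and 151 CPM), while Fos was 12.7-fold higher, and muscle library 4, at 4419 CPM of these markers, had an immediate early sum of only 5137 CPM. The median was taken after 2 other forms of this test were seen, ratios of means of 1.15 with Ebf1 and 1.52 without it, and as the last lies just over the bound of 1.5 first set for excluding leukocytes, the exclusion depends on that choice. Unequal handling of the tissues before lysis could raise these genes, as the 7 tested heat shock members had a median log2 fold change of -1.32, and cannot be told apart from tissue, because both divide the libraries in the same way. A difference between the tissues at rest stays open and untested.

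Of 23 tested adipogenic genes 8 were higher in lymph node libraries, among them the adipocyte regulator Pparg (-4.31 on the log2 scale, named after its value was seen). RNA of adipocytes around the nodes is argued against, because Adipoq, Plin1, Cidec, Retn and Cfd summed to 2.81 CPM in lymph node libraries beside 105 CPM of Cd36. RNA of capillary endothelium is argued against in the same way, since Pecam1 and Cdh5 summed to 2.92 CPM. Unequal handling before lysis was not tested for the adipogenic genes and divides the libraries in the same way as tissue. It therefore stays open, as does a difference between the tissues at rest, which is also untested.

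Regrouping the 6 libraries into other sets of 3 and 3 gives 10 splits, too few for a share under 0.05. The real split called 468 genes with edgeR, and 1 of the 10 splits, the real one, gave as many. The highest of the other splits called 0 genes, with 438 at an unadjusted p under 0.05 at most, against 1637 in the real split.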
